A study of Rattus norvegicus with 48 samples.

How the data were processed

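Total RNA from kidneys of male rats was hybridised to exon arrays, 1 array per sample, with biotin-labelled targets made after removal of ribosomal RNA, per the labels' protocols. The 48 arrays were grouped by the strain and day in their labels, which gives 12 groups of 4 arrays (strains F, L, FL and LF at days 0, 7 and 10). The labels state 8 rats per group and the series' design calls the 4 samples of a group biological replicates. Whether an array holds RNA of 1 rat or of several is not given, so p-values measure the spread between these arrays.

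The authors' deposited values are log2 intensities, 1 per probe set and array, made with RMA (background correction, quantile normalization and probe summary) per the submitters' processing notes, which name RMA and limma without versions. Software settings, a detection filter and the annotation the authors used are not given in the sources used here. The values cover 92401 probe sets, with 0 missing values, and the array medians over these rows are not equal (6.03 to 6.61). The first principal component of the gene values (25.4% of the variance) had an R-squared of 0.952 with the array median. No step to equalise the arrays was added in the main analysis, and quantile normalization was run as an alternative.

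Probe sets were named through the platform annotation. Of the 92401 probe sets 85406 had 1 gene symbol, 1803 several and 5192 none, and those with several or none were kept out of the gene tests. Of 8016 symbols 6113 were current in the GRCr8 annotation, 1876 were updated through a synonym and 27 were kept as the platform gives them. The gene table served for names, chromosomes and neighbours, and no coordinates were used. A gene value was the Tukey median polish of the log2 values of its probe sets over the 48 arrays, which gave 7997 genes with a median of 9 probe sets. Of these 487 had 1 probe set, and 7001 had 3 or more, the number required of a gene named for its size of change.

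Gene values were fitted with limma (version 3.58.1, in R 4.3.3 with data.table version 1.17.8) in 1 linear model with a mean for each of the 12 groups, so that every comparison shared 1 estimate of the spread, moderated with eBayes. Log2 differences are given with their limma SE, and group levels with the SD of 4 arrays. Benjamini-Hochberg adjustment ran over all 7997 genes within each comparison, and a call is an adjusted p under 0.05. The comparisons were days 7 and 10 against day 0 and against each other as means of 4 strains, days 7 and 10 against day 0 within each strain, all pairs of strains at day 0, 3 differences of day 10 responses and an F test of 6 interaction contrasts. Use of probe sets was tested with limma diffSplice. A further 28 lists of genes (pathways and markers of kidney segments and of other cell types), fixed before the data were examined, were tested with limma camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The chromosomes of called genes were tested with two-sided Fisher's exact tests. Figures were drawn with matplotlib 3.10.9.

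The genes named were fixed by rule before the data were examined. For days 7 and 10 as means of strains and for F minus L they are the 10 with the largest rise and the 10 with the largest fall among genes past the test with 3 or more probe sets and the same direction in the 4 replicate numbers. For other comparisons they are the 5 and 5 by that rule, for the interaction the 10 and for probe set use the 5 with the smallest p, from each list up to 4 members with the smallest adjusted p, and always Cyp1a1, Agt and Ace. A further gene of the rule is not reported here. Levels of Hmox1, Havcr1, Mx2 and Dnajb12 in comparisons outside the rule, and Dnajb12, clock genes, Grik2 and Cacng5 in observations over several times, were chosen after their values were seen.

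The replicate number was checked as a batch, because the array file names in the labels share a start within a number. Deviations from group means correlated at a mean of 0.0948 over 264 pairs of arrays with the same number (112 pairs over 0.1, lowest -0.301) and at -0.0316 over 792 pairs with different numbers, and 29 of 48 arrays matched best with an array of their own number. The first principal component of the deviations (27.6% of the variance) had an R-squared of 0.533 with the number and 0.692 with the array median. Mean array medians were 6.45, 6.39, 6.32 and 6.22 for numbers 1 to 4. The number was taken to pair the arrays through the labels. It was left out of the main model, as fixed before the data were examined, and a fit with it as a block was run for every result.

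Alternatives fixed in advance were the replicate block, quantile normalization on top of the deposited values, the mean of probe sets in place of median polish, leaving out the dimmest genes (the lowest 33.3% by mean value), a fit on the compared groups alone, the estimated correlation for lists, and leaving out each array or all arrays of a replicate number. Added after the data were seen were leaving out strain LF and taking strain differences over the mean of 3 times or of days 7 and 10. Calls were also counted over other splits of the arrays, every split into 4 and 4 arrays or 100 random splits, and 40 for probe set use.

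Of the tests, 5 limma comparisons, the interaction, diffSplice for F minus L and camera at day 10 were run on simulated data with the spread of these arrays, and the chromosome test was not. In these data 200 of 7997 genes were changed, and noise was drawn separately for each gene and array. They hold no correlation between genes, no batch and no shift of whole arrays. Their shares of false calls may thus not hold for the real arrays. For changes of 1 log2 unit limma recovered 100% of genes for day 7 and for day 10, and 94% for F minus L. For changes of 0.5 it recovered 93%, 94% and 51%. False calls made up 4.93%, 3.0% and 5.84% of calls. The day 10 comparison within strain L recovered 95% and 56% at the 2 sizes. Camera recovered 2 of 2 changed lists at day 10 with 0 false, but random splits of the real arrays gave up to 11 lists. DiffSplice on 7510 genes recovered 73% with 27.7% of calls false, and with 1 spread per gene 67% with 6.29% false.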

Results

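Kidney RNA of male rats was measured on exon arrays, which read most genes through several probe sets. The 48 arrays covered 4 strains, named F, L, FL and LF in the labels, at 3 times, with 4 arrays in each of the 12 groups. Treated animals received indole-3-carbinol, a plant compound whose products activate the aryl hydrocarbon receptor, by gavage at 100 mg/kg/day for 7 or 10 days. Day 0 animals received the carrier, vegetable oil. Every day 7 and day 10 group had the compound, and no group had the carrier at those days. An effect of the compound thus cannot be told apart from one of the days of gavage or of collection. Induction below means the difference from day 0. The labels neither expand the strain names nor state a purpose. From knowledge of the study outside the labels, the compound was used to raise blood pressure through a transgene under the Cyp1a1 promoter, and the strains served to find genes that modify the kidney damage that follows. The median log2 value of an array lay between 6.03 and 6.61, with a mean of 6.38 ± 0.12 at day 0, 6.28 ± 0.13 at day 7 and 6.37 ± 0.16 at day 10 (SD, n = 16 arrays each). The number of arrays limits the precision of every value below, and p-values measure the spread between these arrays.

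Cyp1a1, the cytochrome P450 that the aryl hydrocarbon receptor induces, was read first because it reports exposure to the compound. In strain F its mean log2 value was 4.52 ± 0.31 at day 0, 6.95 ± 1.41 at day 7 and 7.14 ± 0.44 at day 10 (SD, n = 4 arrays each). The values in strain L were 4.12 ± 0.21, 5.48 ± 0.35 and 5.32 ± 0.34. Strain FL gave 4.71 ± 0.24, 5.26 ± 0.75 and 6.56 ± 0.54, and strain LF 4.94 ± 0.23, 5.43 ± 0.46 and 5.44 ± 0.83. Cyp1a1 rose past the limma test in strain F at day 7 (log2 change 2.43 ± 0.41, SE, adjusted p = 0.000911, or 0.108 in a fit on the compared groups alone, and 1.78 without F day 7 replicate 3) and at day 10 (2.62 ± 0.41, adjusted p = 0.00078). It did not pass within strain L (1.36 ± 0.41 and 1.20 ± 0.41, adjusted p = 0.636 and 0.864). Neither did it in FL (0.55 ± 0.41 and 1.85 ± 0.41, adjusted p = 0.85 and 0.0756) or LF (0.49 ± 0.41 and 0.51 ± 0.41, adjusted p = 0.522 and 1). The day 10 response of F minus that of L was 1.42 ± 0.57 (adjusted p = 0.794), so the Cyp1a1 responses of F and L were not shown to differ. Its interaction over all strains and times had adjusted p = 0.297.

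**Figure D1:**
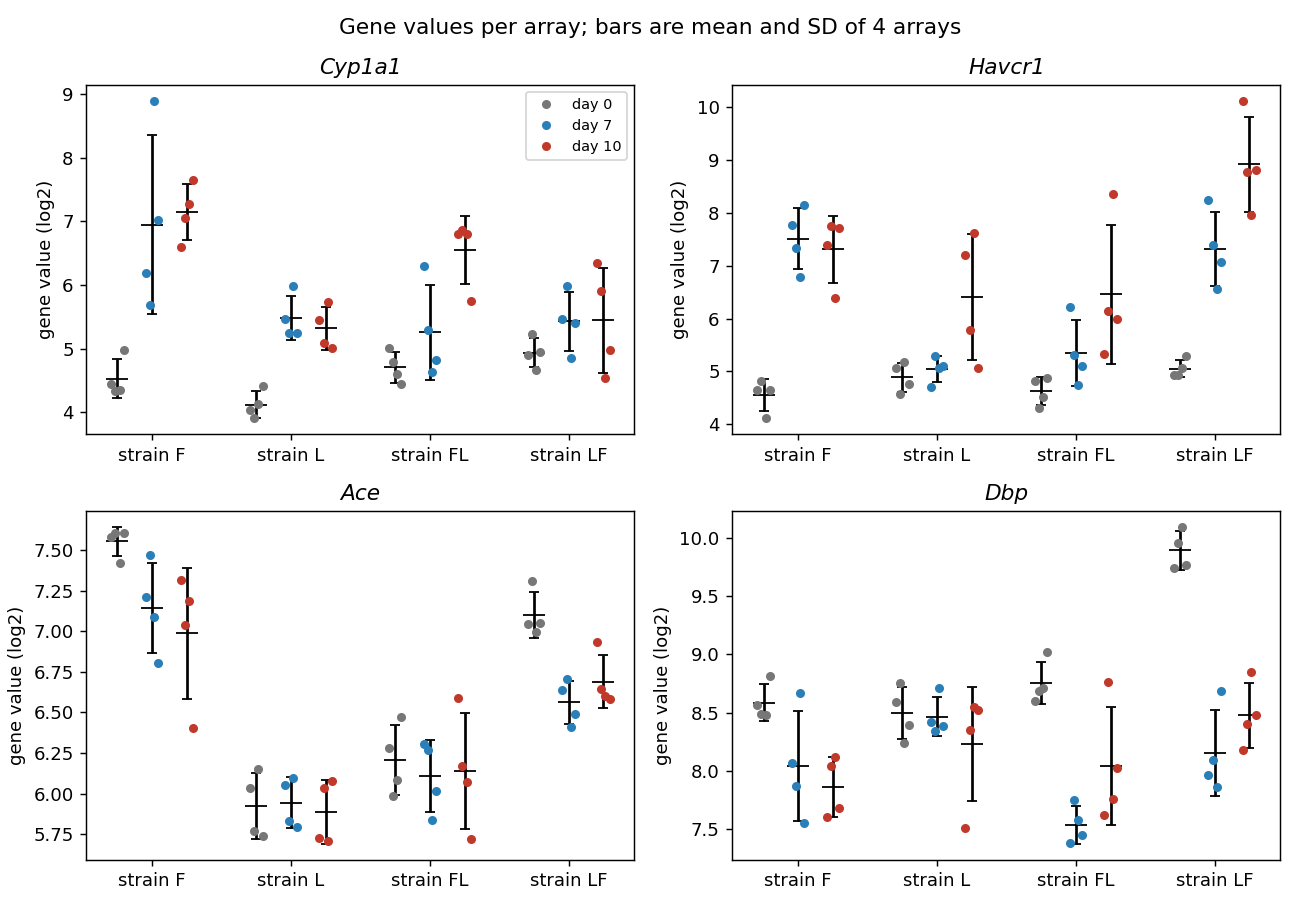
Log2 gene values (vertical axis) of Cyp1a1, Havcr1, Ace and Dbp in each array, by strain and day, with bars for the mean and SD of 4 arrays. Mean Havcr1 was 8.92 in strain LF at day 10, against 5.05 in that strain at day 0.

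Averaged over the 4 strains, Hmox1, heme oxygenase, rose 3.19-fold after 7 days of induction (log2 change 1.67 ± 0.44, SE, n = 16 arrays against 16, limma adjusted p = 0.0178), and Havcr1, the kidney injury molecule of the proximal tubule, rose 2.87-fold (1.52 ± 0.23). Mean Hmox1 at day 7 was 7.82 ± 1.85 in F and 8.61 ± 2.18 in LF (SD, n = 4). In L (4.54 ± 0.39) and FL (4.92 ± 0.33) it lay near its day 0 level (4.81 and 4.79). Cyp1a1 rose 2.31-fold (1.21 ± 0.20) and Mt1, a metallothionein, 2.22-fold (1.15 ± 0.17). The sulfotransferase Sult1a1 (log2 change 0.90), the mitochondrial carrier Slc25a25 (0.79), the serine protease inhibitor Serpina3n (0.68), the fibrinogen chain Fga (0.68), the pyruvate dehydrogenase kinase Pdk4 (0.68) and Angptl4 (0.67) also rose. The interferon-induced Mx2 fell 2.29-fold (-1.19 ± 0.18), and Mx1 (-0.96), Oasl2 (-0.91) and Slfn3 (-0.92) fell with it. The B cell chemokine Cxcl13 (-1.15), the distal tubule calcium handling genes Calb1 (-0.90) and Slc8a1 (-0.90), and the clock output genes Dbp (-0.88) and Nr1d1 (-0.86) fell as well. The BMP antagonist Grem1 fell 2.01-fold. The same direction in all 4 replicate numbers was part of the rule that chose these 20 genes. Angiotensinogen, Agt, differed by -0.01 ± 0.07 (adjusted p = 0.974). The angiotensin-converting enzyme gene Ace differed by -0.26 ± 0.08 (adjusted p = 0.0517), which passed with the replicate number as a block (adjusted p = 0.0203).

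The limma test called 398 of 7997 genes at day 7, 88 higher and 310 lower. With the replicate number as a block it called 894, 155 higher and 739 lower, and after quantile normalization the split was 231 higher and 326 lower. Without strain LF, left out after the data were seen, 67 genes were called, and the arrays of replicate 2 left out gave 71. Without LF, Hmox1 (0.88, adjusted p = 0.56), Sult1a1 (0.72), Slc25a25 (0.70), Serpina3n (0.36), Fga (0.52), Pdk4 (0.52), Angptl4 (0.57) and Slfn3 (-0.66) no longer passed, and without L day 0 replicate 4 the count was 674.

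Among the gene lists fixed in advance, the interferon response list had the smallest camera p at day 7 with the preset correlation and did not pass with an estimated one. Of its 14 measured members 9 fell and 5 did not pass (11 fell when adjusted over the list alone), with Gbp2 at -0.60 ± 0.10 (limma camera adjusted p = 8.73e-12, adjusted p = 0.0765 with an estimated correlation). In the tubular injury list 7 of 22 members rose and 0 fell (10 rose and 2 fell when adjusted over the list alone), among them Clu at 0.46 ± 0.11 and Timp1 at 0.50 ± 0.10. The injury list had adjusted p = 1.42e-08, and adjusted p = 0.0534 with an estimated correlation. Markers of the loop of Henle and distal nephron fell in 7 of 16 members (9 when adjusted over the list alone), with Kl, the co-receptor klotho, at -0.35 ± 0.06 and the potassium channel Kcnj1 at -0.26 ± 0.06. The distal nephron list had adjusted p = 4.67e-07, and adjusted p = 0.254 with an estimated correlation. Collecting duct markers fell in 7 of 17 members (9 fell and 2 rose when adjusted over the list alone), led by the urea transporter Slc14a2 (-0.56 ± 0.06) and the water channel Aqp2 (-0.49 ± 0.08). The collecting duct list had adjusted p = 0.0136, adjusted p = 0.0668 under the block and adjusted p = 0.525 with an estimated correlation. Among 24 proximal tubule markers 5 fell (8 when adjusted over the list alone), with the transporter Slco1a1 at -0.41 ± 0.12 (adjusted p = 0.00817, adjusted p = 0.525 with an estimated correlation, and adjusted p = 0.128 without LF).

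Antigen presentation genes fell in 5 of 18 members at day 7 (8 when adjusted over the list alone), with the class I gene RT1-CE5 at -0.39 ± 0.09 and B2m at -0.27 ± 0.07 (camera adjusted p = 0.000935, adjusted p = 0.381 with an estimated correlation). Macrophage and monocyte markers fell in 4 of 19 members (9 fell and 1 rose when adjusted over the list alone), with the Fc receptor Fcgr3a at -0.61 ± 0.13 and Adgre1 at -0.38 ± 0.11. The macrophage list had adjusted p = 0.00331, adjusted p = 0.445 with an estimated correlation and adjusted p = 0.0966 without LF. In the circadian clock list 6 of 13 members fell and 2 rose (6 fell and 3 rose when adjusted over the list alone), with Per3 at -0.51 ± 0.07 and Bhlhe41 at -0.68 ± 0.10. The clock list had adjusted p = 0.000934, adjusted p = 0.254 with an estimated correlation and adjusted p = 0.0234 without LF. Genes of fatty acid oxidation and peroxisomes rose in 4 of 29 members and fell in 1 (6 rose and 2 fell when adjusted over the list alone), with Ehhadh at 0.38 ± 0.07 and Eci1 at 0.48 ± 0.10. The fatty acid list had adjusted p = 0.00051, and adjusted p = 0.457 with an estimated correlation. Of 10 aryl hydrocarbon receptor targets, Cyp1a1 alone rose (adjusted p = 0.00506, adjusted p = 0.0986 with an estimated correlation), and Nqo1 differed by 0.19 ± 0.12. Among 12 renin-angiotensin genes the peptidases Mme (-0.26 ± 0.07) and Anpep (-0.23 ± 0.07) fell (4 fell when adjusted over the list alone). The renin-angiotensin list had adjusted p = 0.0472, adjusted p = 0.0668 under the block, adjusted p = 0.445 with an estimated correlation and adjusted p = 0.063 without LF. Red cell transcripts moved at the same time, with Hba-a2 at 0.26 ± 0.08 and 1 of 5 members past the test (4 when adjusted over the list alone, adjusted p = 0.000701, adjusted p = 0.018 with an estimated correlation). In all, 15 of 28 lists passed the camera test at day 7, and with an estimated correlation 1 did, the red cell list.

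The mean over strains at day 10 showed a tubular injury signal in many genes. Havcr1 rose 5.63-fold (log2 change 2.49 ± 0.23, SE, n = 16 arrays against 16, limma adjusted p = 2.04e-09), Hmox1 3.68-fold (1.88 ± 0.44), Cyp1a1 2.92-fold (1.55 ± 0.20), Mt1 2.36-fold (1.24 ± 0.17) and Clu, the chaperone clusterin, 2.03-fold (1.02 ± 0.11). Hmox1 varied within groups at day 10, at 7.77 ± 1.76 in F, 6.21 ± 1.90 in L, 7.09 ± 2.40 in FL and 5.66 ± 0.37 in LF (SD, n = 4). The fibrinogen chains Fgb (0.99) and Fga (0.88), the neutrophil gelatinase lipocalin Lcn2 (0.93), Slc25a25 (1.02) and Pdk4 (0.83) rose too. Calb1 (-0.84), Slc8a1 (-0.73), Grem1 (-0.79), Nr1d1 (-0.79), Dbp (-0.78), the stearoyl-CoA desaturase Scd (-0.75), Cxcl13 (-0.70), the channel Mcoln3 (-0.68), the chemokine Cxcl12 (-0.66) and the growth factor Igf1 (-0.66) fell. These 20 genes were chosen by the same rule. Agt differed by -0.02 ± 0.07 (adjusted p = 0.997) and Ace by -0.27 ± 0.08 (adjusted p = 0.064, or 0.0296 with the replicate number as a block and 0.00361 after quantile normalization). At day 10 limma called 184 genes, 99 higher and 85 lower, and 349 after quantile normalization. Without strain LF it called 76, with Lcn2 (0.38, adjusted p = 0.365) and Cxcl13 (-0.69, adjusted p = 0.0956) no longer past, and without the arrays of replicate 3 it also called 76.

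The tubular injury list held its call at day 10 with the preset and the estimated correlation. Of its 22 members 12 rose, 1 fell and 9 did not pass, the same numbers when adjusted over the list alone, with Havcr1, Clu, Lcn2 and Timp1 (0.78 ± 0.10) among those that rose (camera adjusted p = 1.98e-21, adjusted p = 0.000425 with an estimated correlation). Fatty acid oxidation and peroxisome genes rose in 4 of 29 members (10 when adjusted over the list alone), with Ehhadh at 0.41 ± 0.07 and Pex11a at 0.44 ± 0.10 (adjusted p = 1.97e-09, adjusted p = 0.251 with an estimated correlation). Complement and coagulation genes rose in 6 of 19 members (8 when adjusted over the list alone), with C4b at 0.46 ± 0.07 and Serpina3n at 0.78 ± 0.15 (adjusted p = 1.35e-07, adjusted p = 0.0754 with an estimated correlation). The immediate early genes Myc (0.43 ± 0.09), Klf6 (0.45 ± 0.10), Jun (0.35 ± 0.09) and Atf3 (0.50 ± 0.12) rose, 4 of 15 members (also 4 when adjusted over the list alone), with adjusted p = 3.95e-07 and adjusted p = 0.0754 with an estimated correlation. Smooth muscle, mesangium and pericyte markers rose in 4 of 14 members (8 rose and 1 fell when adjusted over the list alone), with the contractile gene Tagln at 0.60 ± 0.07 (adjusted p = 1.42e-07, adjusted p = 0.0754 with an estimated correlation).

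Loop of Henle and distal nephron markers fell at day 10 in 4 of 16 members (7 when adjusted over the list alone), with Kl at -0.30 ± 0.06 (camera adjusted p = 1.2e-08, adjusted p = 0.148 with an estimated correlation). Collecting duct markers fell in 6 of 17 members and rose in 1 (8 fell and 4 rose when adjusted over the list alone), with Aqp2 at -0.61 ± 0.08 and Slc14a2 at -0.47 ± 0.06 (adjusted p = 0.0013, adjusted p = 0.486 with an estimated correlation). Among 13 clock genes 5 fell and 1 rose (6 fell and 3 rose when adjusted over the list alone), a list call lost without LF (adjusted p = 0.00151 with it, adjusted p = 0.259 without it, and adjusted p = 0.251 with an estimated correlation). In the oxidative stress list of the transcription factor NRF2, 3 of 15 members rose (also 3 when adjusted over the list alone), including Hmox1, Mt1 and the glutathione peroxidase Gpx2 at 0.40 ± 0.06. The NRF2 list had adjusted p = 0.0201, adjusted p = 0.0548 under the block and adjusted p = 0.486 with an estimated correlation. The aryl hydrocarbon receptor list passed with Cyp1a1 as its 1 member of 10 to rise (3 when adjusted over the list alone), with adjusted p = 0.00153 and adjusted p = 0.0754 with an estimated correlation. Red cell transcripts did not pass (Hba-a2 at -0.01 ± 0.08). At day 10 12 of 28 lists passed the camera test, and 1 did with an estimated correlation.

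**Figure D2:**
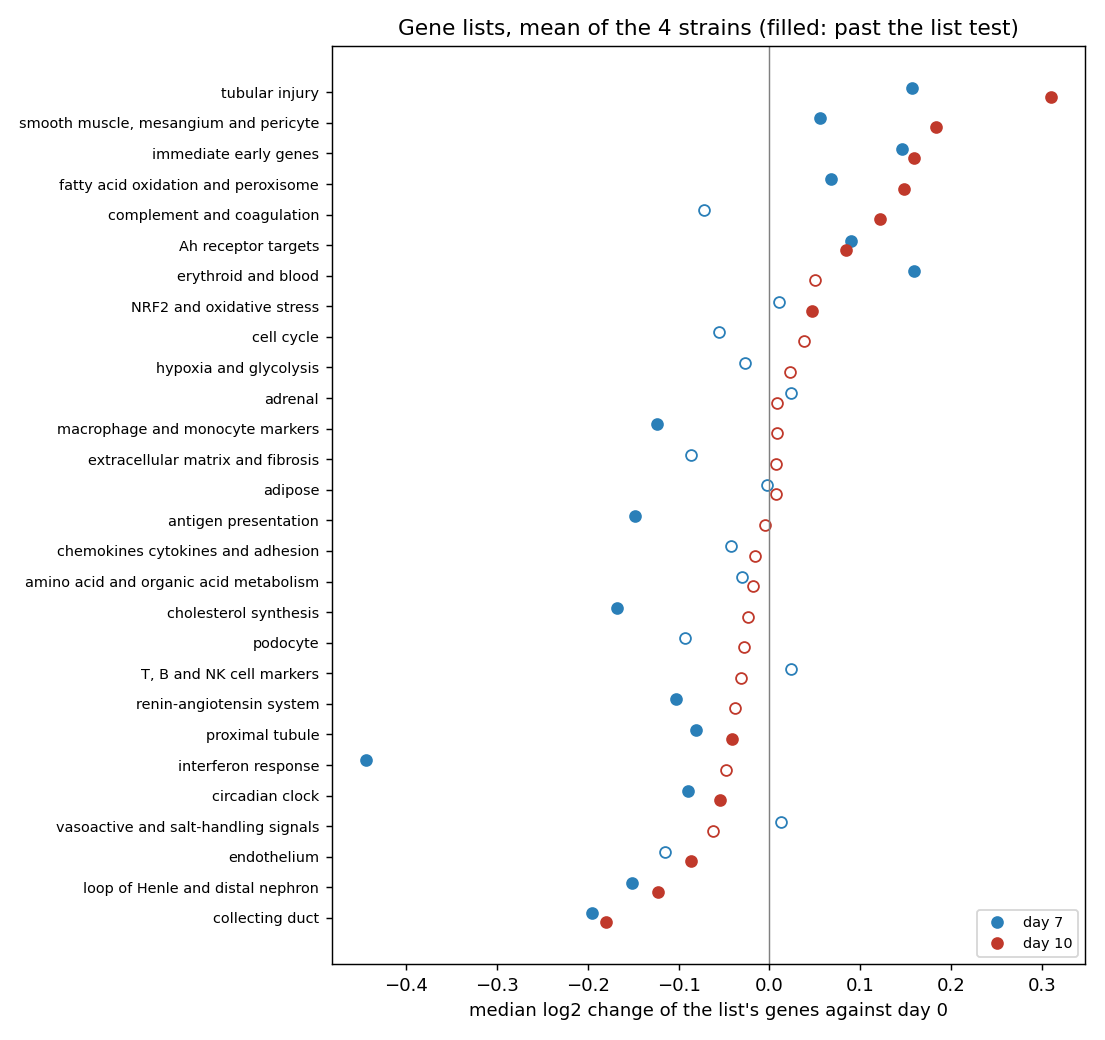
Median log2 change against day 0 (horizontal axis) of the genes in each fixed list (rows) at day 7 and day 10, mean of 4 strains, with filled points for lists past the camera test. The tubular injury list had a median of 0.157 at day 7 and 0.31 at day 10, and the interferon list -0.444 at day 7 and -0.0477 at day 10.

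Set directly against day 7 as a mean of strains, Mx2 was 1.91-fold higher at day 10 (log2 difference 0.93 ± 0.18, SE, n = 16 arrays against 16, limma adjusted p = 0.0331), and Slfn3 (0.72 ± 0.15, adjusted p = 0.0478, or 0.0524 under the block), Apol9a (0.47 ± 0.10) and Oas2 (0.43 ± 0.09) were higher as well. From day 7 to day 10 mean Mx2 went from 5.08 ± 0.20 to 7.88 ± 0.77 in LF, from 5.77 ± 0.41 to 6.47 ± 0.85 in L, from 5.65 ± 0.59 to 5.88 ± 0.73 in FL and from 5.53 ± 0.17 to 5.54 ± 0.62 in F (SD, n = 4). Clu was 1.47-fold higher (0.56 ± 0.11), while Havcr1 (0.97 ± 0.23, adjusted p = 0.0902) and Cyp1a1 (0.34 ± 0.20, adjusted p = 0.444) did not pass. Of the 14 interferon list members 1 was higher over all genes tested and 12 when adjusted over the list alone (camera adjusted p = 4.93e-12, adjusted p = 0.107 with an estimated correlation). The test called 6 genes, all higher, and 1051 had an unadjusted p under 0.05. Without strain LF limma called 0 genes (Mx2 at 0.31, adjusted p = 0.968), as it did in a fit on day 7 and day 10 arrays alone and without any of several single arrays from each of the 4 strains. Leaving out single arrays gave between 0 and 55.

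Within strain F, Havcr1 and Mt1 rose at both times. At day 7 Havcr1 rose 7.75-fold (log2 change 2.95 ± 0.47, SE, n = 4 against 4, limma adjusted p = 0.000666), Mt1 5.51-fold (2.46 ± 0.34), Slc25a25 3.71-fold (1.89 ± 0.38) and Sult1a1 2.98-fold (1.57 ± 0.35). Scd fell 2.83-fold, and Nr1d1 (-1.42 ± 0.25), Grem1 (-1.36 ± 0.28), Calb1 (-1.32 ± 0.24) and Slc8a1 (-1.30 ± 0.26) fell. At day 10 Havcr1 (2.75 ± 0.47), Mt1 (1.96 ± 0.34), Clu (0.96 ± 0.22) and the proton pump Atp12a (0.95 ± 0.21) rose, and Calb1 (-1.49 ± 0.24), Nr1d1 (-1.40 ± 0.25), Scd (-1.26 ± 0.28), Grem1 (-1.23 ± 0.28) and Cacng5 (-1.15 ± 0.24) fell. Ace in F differed by -0.41 ± 0.16 at day 7 (adjusted p = 0.444) and -0.57 ± 0.16 at day 10 (adjusted p = 0.139, or 0.0391 after quantile normalization). The counts in F were 55 genes at day 7, 35 higher and 20 lower, and 30 at day 10, 11 higher and 19 lower, which became 37 higher and 29 lower after quantile normalization and 52 genes in all under the block. Without F day 0 replicate 2 the day 10 count was 7, and on the compared groups alone it was 16, with Clu (adjusted p = 0.111) and Atp12a (adjusted p = 0.358) no longer past.

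Strain L gave no call at either time. Limma called 0 genes at day 7 and 0 at day 10, where 340 and 336 genes had an unadjusted p under 0.05. Both numbers are under 5% of the 7997 genes tested, the share such a bound gives without any change. With the block it called 0 at day 7 and 1 at day 10, and after quantile normalization 0 and 2. Havcr1 in L differed by 0.15 ± 0.47 at day 7 (adjusted p = 0.998) and by 1.52 ± 0.47 at day 10 (adjusted p = 0.864), and Mx2 by -1.21 ± 0.35 at day 7 (adjusted p = 0.564). On simulated data, limma recovered 95% of genes changed by 1 log2 unit and 56% of those changed by 0.5 in the day 10 comparison of this strain. Those data had 200 changed genes, separate noise for each gene and array, and the spread pooled over all groups. In the real arrays Havcr1 changed by over 1 log2 unit at day 10 (SD 1.19 in L) and was not called. The absence of calls thus does not exclude changes of that size in L.

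In strain FL the leading changes were a rise of Dnajb12, a co-chaperone of the endoplasmic reticulum membrane, and falls of the stress response genes Nupr1 and Asns. Dnajb12 was 5.87-fold higher at day 7 (log2 change 2.55 ± 0.27, SE, n = 4 against 4, limma adjusted p = 4.75e-08) and 6.45-fold higher at day 10 (2.69 ± 0.27), against a low day 0 mean of 5.48 ± 1.29 (SD). Without FL day 0 replicate 4 (7.40, where the others were 4.65 to 5.06) the log2 changes were 3.19 and 3.33. Nupr1 fell at both times (-1.90 ± 0.23 and -1.23 ± 0.23), and at day 7 Dbp (-1.21 ± 0.21), Asns (-1.02 ± 0.17), Septin4 (-0.94 ± 0.18) and Per3 (-0.82 ± 0.14) fell and Tagln rose (0.69 ± 0.15). Limma called 12 genes in FL at day 7, 2 higher and 10 lower (6 and 14 after quantile normalization, and 19 in all under the block), and 2 at day 10 (4 under the block). Fitted on the compared groups alone, 2 genes passed at day 7 and 1 at day 10, and Dnajb12 was lost at both times (adjusted p = 0.266 and 0.217).

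Strain LF had the highest counts of the 4 strains, measured against a day 0 group whose clock genes stood apart. The clock score, the mean log2 value of 7 clock output genes less that of 3 genes in the opposite phase, was 2.90 ± 0.17 in LF at day 0 (SD, n = 4). At day 0 it was 1.03 ± 0.20 in F, 1.02 ± 0.30 in L and 1.43 ± 0.34 in FL, and in LF it was 0.90 ± 0.40 at day 7 and 1.12 ± 0.23 at day 10. At day 7 Hmox1 rose 16.6-fold (log2 change 4.06 ± 0.88, SE, n = 4 against 4, limma adjusted p = 0.00616, or 0.0514 on the compared groups alone), from 4.56 ± 0.10 to 8.61 ± 2.18 (SD). Replicate 4 at day 7 was 5.47 where the others were 8.85 to 10.23, and without it the log2 change was 5.10. Havcr1 (2.27 ± 0.47), the clock gene Bmal1 (1.82 ± 0.30), Lcn2 (1.72 ± 0.26) and Serpina3n (1.66 ± 0.30) rose, and Mx2 (-2.12 ± 0.35), Cxcl13 (-2.03 ± 0.34), Dbp (-1.74 ± 0.21), Mx1 (-1.70 ± 0.29) and Slfn3 (-1.69 ± 0.31) fell. At day 10 Havcr1 was 14.6-fold higher than at day 0 (3.87 ± 0.47, adjusted p = 8.53e-07) and Lcn2 5.91-fold higher (2.56 ± 0.26, or 1.95 with the mean of probe sets), with Clu (1.83 ± 0.22), Bmal1 (1.71 ± 0.30) and the phosphate transporter Slc34a2 (1.62 ± 0.21) also up. Gadd45g (-1.46 ± 0.32), Dbp (-1.41 ± 0.21), Bhlhe41 (-1.24 ± 0.20), the carboxylesterase Ces1e (-1.20 ± 0.19) and Ptprq (-0.96 ± 0.15) fell at day 10. Hmox1 was at 5.66 ± 0.37 at day 10 (SD), below its day 7 mean. Ace in LF differed by -0.54 ± 0.16 at day 7 (adjusted p = 0.0629, or 0.0219 under the block). The test called 195 genes in LF at day 7, 31 higher and 164 lower (152 and 184 after quantile normalization, and 683 in all under the block), and 83 at day 10, 54 higher and 29 lower. The day 7 count fell to 66 on the compared groups alone and to 60 without LF day 0 replicate 2.

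The comparisons within F and within LF share no arrays. They share 1 spread per gene in the fit and the replicate numbers, so the numbers given for independent lists are a reference and not a test. At day 7 the 55 genes called in F and the 195 called in LF shared 21, of which 20 moved the same way, where independent lists of these sizes would share 0.546 in the same direction. At day 10 the 30 and 83 genes called shared 8, all in the same direction, against 0.143. The 2 genes called in FL and the 83 in LF shared 0. In L, where 0 genes were called at day 10, 29 of the 30 genes called in F had the same sign as in F (correlation across these genes 0.911). Genes are not independent replicates, so this carries no test.

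Responses that differed between strains were tested as interactions. The Dnajb12 response at day 10 was larger in FL than in F by 2.71 ± 0.38 (log2, SE, limma adjusted p = 7.91e-05, or 3.35 without FL day 0 replicate 4), the 1 gene called in that comparison. At day 10 Dnajb12 was at 8.16 ± 0.22 in FL and 8.06 ± 0.15 in F (SD, n = 4). The difference thus lies in the low FL day 0 values (5.48 ± 1.29, where F was at 8.08 ± 0.04). On the compared groups alone 0 genes were called, and 6 of 100 random splits, the real one included, gave 1 gene or more. The LF response exceeded that of L for Lcn2 (1.93 ± 0.37, adjusted p = 0.0208) and lay below it for Ces1e (-1.55 ± 0.27, adjusted p = 0.00778) and Acaa2, a mitochondrial thiolase (-0.90 ± 0.18, adjusted p = 0.0231). These 3 genes, 1 higher and 2 lower, were the ones called, and the split became 7 higher and 6 lower after quantile normalization and 11 in all under the block. Havcr1 responded by 2.34 ± 0.66 more in LF than in L, which did not pass (adjusted p = 0.434). Between F and L limma called 0 genes, with 479 at an unadjusted p under 0.05, 0 under the block and 0 after quantile normalization, and Havcr1 differed by 1.23 ± 0.66 (adjusted p = 0.794). Over all strains and times 16 genes had an interaction past the limma F test, with the smallest p for Dnajb12 (adjusted p = 1.41e-05), then Ndrg1, Lcn2, Per2, Slfn3, Sik1, Ptprq, Per3, Acaa2 and Mx2 (adjusted p = 0.0235). That count was 28 under the block, 3 without strain LF and 0 without the arrays of replicate 2. At day 0 LF stood apart in Per3 (7.22 ± 0.16, SD, other strains 6.13 to 6.38) and Ndrg1 (11.2 ± 0.15, other strains 11.8 to 12.1). The interactions of Per3 and Ndrg1 rest in part on that group. On simulated data 80% of interactions of 1 log2 unit were recovered, and 72% of such differences between the responses of F and L. These shares hold for 200 genes changed at the simulated spread.

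Gene lists for the F response minus the L response gave 6 calls, of which 0 passed with an estimated correlation, and 1 list passed without the arrays of replicate 4. The calls were tubular injury, by camera in the upward direction, and the cell cycle, collecting duct, loop of Henle and distal nephron, amino acid metabolism and renin-angiotensin lists in the downward one. No member of these lists passed over all genes tested. The tubular injury list, with a median of 0.0416, had an adjusted p of 0.0197 (adjusted p = 0.801 with an estimated correlation), and the cell cycle list, with a median of -0.454, an adjusted p of 0.0148 (adjusted p = 0.488 with an estimated correlation). After quantile normalization 2 lists passed.

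Akr1c2, Cyp2d5, Acsm5 and Ace were among the genes that differed between strains F and L at day 0. Akr1c2, an aldo-keto reductase, was 7.05-fold higher in F (log2 difference 2.82 ± 0.25, SE, n = 4 against 4, limma adjusted p = 1.03e-10), and its relatives Akr1b8 (2.27 ± 0.45) and Akr1b10 (1.48 ± 0.35) were higher too. The probe sets of Akr1c2 did not all differ alike over the 3 times (limma diffSplice adjusted p = 5.79e-50). The membrane proteins Gp2 (1.84 ± 0.26) and Tspan1 (1.70 ± 0.21), Lilrb4 (1.47), the ATP-gated channel P2rx4 (1.41), the RNA editing enzyme Apobec1 (1.23) and the amino acid transporter Slc7a12 (1.20) were higher in F. Ace was 3.1-fold higher in F (1.63 ± 0.16, adjusted p = 2e-09), with log2 values of 7.55 ± 0.09 in F and 5.92 ± 0.20 in L (SD, n = 4). The cytochromes Cyp2d5 (-2.75 ± 0.43), Cyp2c11 (-1.63) and Cyp2d2 (-1.46), the acyl-CoA synthetase Acsm5 (-2.40 ± 0.11, adjusted p = 2.81e-20), the kallikrein Klk1c9 (-1.79), Lcn2 (-1.55), Ces1e (-1.48), Sult1b1 (-1.25), the retinol dehydrogenase Rdh16 (-1.19) and the transporter Abcb10 (-1.17) were lower in F. Agt was lower in F by 0.87 in size (-0.87 ± 0.14, adjusted p = 7.6e-05), and Cyp1a1 differed by 0.40 ± 0.41 (adjusted p = 0.955). Limma called 108 genes, 46 higher and 62 lower in F, and 222 after quantile normalization, against 71 in a fit on the 8 arrays compared, where Apobec1 (adjusted p = 0.0532) and Klk1c9 (adjusted p = 0.0839) were lost. The mean of the 3 times, chosen after the data were seen, gave 562 genes, 199 higher and 363 lower (813 in all under the block), with Ace at 1.31. Over that mean, which takes in the changes after induction, Cyp1a1 passed at 1.23 (limma adjusted p = 0.000264).

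Of the fixed lists, 6 of 28 passed for F minus L at day 0 with the preset correlation and 0 with an estimated one (adjusted p = 0.875 for each), and 3 passed without the arrays of replicate 1. Macrophage and monocyte markers had a median of -0.21 in F (camera adjusted p = 0.0267), fatty acid oxidation genes -0.157 (adjusted p = 0.0291) and smooth muscle markers -0.184 (adjusted p = 0.0326). Cholesterol synthesis genes had a median of 0.216 (adjusted p = 0.0291), cell cycle genes 0.183 (adjusted p = 0.0291) and antigen presentation genes 0.138 (adjusted p = 0.0303). Single members past the test were Pex11a (-0.83 ± 0.20, lower in F) and Acaa2 (0.56 ± 0.12, higher in F) among the fatty acid oxidation genes. Others were Cspg4 (-0.50 ± 0.11) and Notch3 (-0.34 ± 0.09) among the smooth muscle markers, Insig1 (0.49 ± 0.13) in cholesterol synthesis, and RT1-CE5 (-0.91 ± 0.19) in antigen presentation, against its list's direction. No macrophage or cell cycle member passed over all genes tested.

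Probe sets of a gene could also part from one another. For F minus L over the 3 times, limma diffSplice called 422 genes, led by Ces1e, Ctsa, Ufsp2, RT1-CE16 and Ogdh, and for day 10 against day 0 it called 32, led by Havcr1, Fgb, Atp12a, Serpina3n and Clu. At day 10, 6 of 40 splits of the arrays, the real one included, gave as many genes (highest other 1361), so chance cannot be excluded. For F minus L the highest other split gave 283, so the count does not show which of the 422 genes are beyond chance. In F minus L a sequence difference between strains under a probe set gives the same reading as another use of exons. On simulated data for F minus L 27.7% of the calls of this test were false and 73% of changed genes were recovered.

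Strain FL differed from F at day 0 in 6 genes. Dnajb12 was 6.1-fold lower in FL (log2 difference -2.61 ± 0.27, SE, n = 4 against 4, limma adjusted p = 2.57e-08, or -3.25 without FL day 0 replicate 4), Ace 2.55-fold lower (-1.35 ± 0.16, adjusted p = 7.74e-07) and Pitpnm1, a phosphatidylinositol transfer protein, lower by 0.91 in size (-0.91 ± 0.15). Asns, the asparagine synthetase (1.03 ± 0.17), the stress-induced transcription factor Atf5 (0.70 ± 0.12) and Nxph4 (0.78 ± 0.16) were higher. Under the block 11 genes were called. On the 8 arrays compared 1 was called, and Dnajb12 (adjusted p = 0.236), Asns (adjusted p = 0.272), Atf5 (adjusted p = 0.272), Nxph4 (adjusted p = 0.582) and Pitpnm1 (adjusted p = 0.119) were lost. Over the mean of the 3 times, chosen after the data were seen, limma called 28 genes (76 under the block), with Ace at -1.08, Pitpnm1 at -0.84, Dnajb12 at -0.86, and Asns at 0.24 (adjusted p = 0.49).

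Strain LF differed from L at day 0 in 20 genes, 15 higher and 5 lower (26 and 16 after quantile normalization), among them Krt19, a keratin, Ace, Dbp and Bmal1. Krt19 was 2.78-fold higher in LF (log2 difference 1.48 ± 0.29, SE, n = 4 against 4, limma adjusted p = 0.00598) and Ace 2.26-fold higher (1.18 ± 0.16, adjusted p = 2.41e-05). The clock genes Dbp (1.40 ± 0.21), Bhlhe41 (1.08 ± 0.20) and Per3 (0.83 ± 0.14) were higher and Bmal1 lower (-1.90 ± 0.30). Also lower were Cacng5 (-1.09 ± 0.24), the glutamate receptor Grik2 (-1.08 ± 0.18), Ndrg1 (-0.85 ± 0.10) and Ppard (-0.56 ± 0.12, adjusted p = 0.0214, or 0.0541 after quantile normalization). Agt differed by -0.18 ± 0.14 (adjusted p = 1). Set against L over days 7 and 10, an alternative chosen after the data were seen, LF still had higher Krt19 (1.21) and Ace (0.71) and lower Grik2 (-1.45), whereas Dbp (-0.03), Bhlhe41 (-0.05), Per3 (0.01), Bmal1 (-0.13), Ndrg1 (0.00), Cacng5 (-0.34) and Ppard (-0.07) did not pass. On the 8 arrays compared 11 genes were called, and Bhlhe41, Cacng5 and Ppard were lost (adjusted p = 0.185, 0.366 and 0.144).

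**Figure D3:**
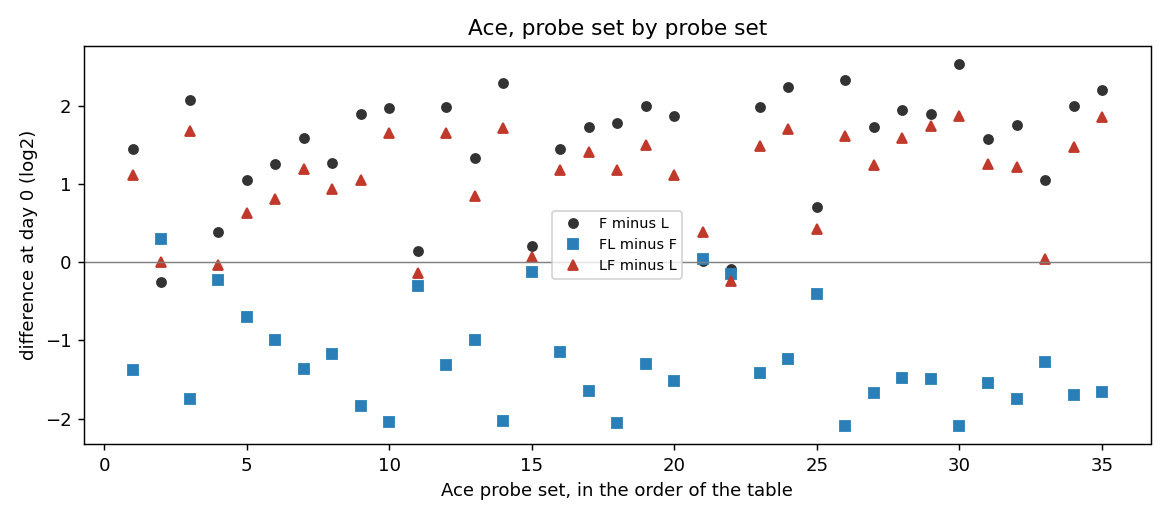
Difference in log2 value at day 0 (vertical axis) for each Ace probe set (horizontal axis, in the order of the table) between F and L, FL and F, and LF and L. Of the 35 probe sets 33 were higher in F than in L, 33 lower in FL than in F and 32 higher in LF than in L.

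Ace was the 1 gene called in both FL minus F and LF minus L, in opposite directions, where independent lists of these sizes would share 0.0075 genes in opposite directions. Its day 0 values placed F (7.55 ± 0.09) and LF (7.10 ± 0.14) above FL (6.20 ± 0.22) and L (5.92 ± 0.20, SD, n = 4 arrays each). FL minus LF was -0.90 ± 0.16 (limma adjusted p = 0.000343) and LF minus F was -0.45 ± 0.16 (adjusted p = 0.186, or 0.00496 after quantile normalization). Ace lies on chromosome 10 in the GRCr8 gene table, as do Krt19 and Cacng5. Of the genes called in either comparison, 4 of 677 tested on chromosome 10 were called, and 5 of 308 on chromosome 20, the 1 chromosome past the two-sided Fisher's exact test (odds ratio 6.3, adjusted p = 0.0492). That call was lost under the block, after quantile normalization, without the dimmest genes, and in a fit on the compared groups alone. It was also lost without the arrays of replicate 1, 2 or 4, and each of these alternatives gave 0 chromosomes called.

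The remaining day 0 pairs followed the split between F and L for most of the leading genes. Akr1c2 was higher in FL than in L (log2 difference 3.14 ± 0.25, SE, n = 4 against 4, limma adjusted p = 3.11e-12) and than in LF (3.14 ± 0.25), and lower in LF than in F (-2.82 ± 0.25). Gp2 (2.17, 2.11 and -1.79 in the same order) and Tspan1 (1.61, 1.59 and -1.68) went the same way, and Acsm5 (-2.65, -2.60 and 2.35), Cyp2d5 (-2.60, -2.42 and 2.58), Ces1e (-1.55, -2.14 and 2.07) and Cyp2c11 (-1.63, -2.01 and 2.01) the opposite way. Slc7a12 (1.31) and Lilrb4 (1.22) were higher in FL than in L, Ptprq was higher in LF than in F (1.75) and Akr1b8 lower (-2.28), and Cacng5 was higher in FL than in LF (1.38). Dnajb12 was lower in FL than in L (-2.59 ± 0.27) and LF (-2.63 ± 0.27), or by -3.23 and -3.27 without FL day 0 replicate 4. With the mean of probe sets Cyp2d5 was at -3.44 in FL minus L and -3.14 in FL minus LF. Bmal1 was lower in LF than in F (-1.89 ± 0.30) and FL, where the difference of FL minus LF was 1.54 ± 0.30. Cyp1a1 did not pass in LF minus F (0.42 ± 0.41, adjusted p = 0.862), but over days 7 and 10 it was lower in LF than in F by 1.61 in size (-1.61, adjusted p = 0.000164, an alternative chosen after the data were seen). In that alternative LF minus F was 1.30 for Ces1e, 0.78 for Ptprq, -1.07 for Tspan1 and -0.14 for Bmal1, and FL minus LF was -1.11 for Ces1e, 0.76 for Cacng5, 0.32 for Bmal1 and 0.04 for Dnajb12. Bmal1 in both and Dnajb12 no longer passed. Limma called 113 genes in FL minus L, 28 higher and 85 lower (115 and 113 after quantile normalization, 185 in all under the block). It called 145 in LF minus F, 93 higher and 52 lower (239 in all under the block), and 202 in FL minus LF, 47 higher and 155 lower (207 and 196 after quantile normalization, 384 in all under the block).

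F minus L and FL minus LF share no arrays, and their calls overlapped, though they too share the spread of the fit and the replicate numbers. The 108 and 202 genes called shared 52, of which 51 went the same way, against 1.47 for independent lists of these sizes, and the log2 differences of all genes correlated across genes at 0.464. FL minus L and LF minus F, which share no arrays either, shared 51 called genes, all in opposite directions, against 1.17 (correlation across genes -0.509). FL minus F and LF minus L shared Ace, with a correlation across genes of -0.064. Genes are not independent replicates, so these correlations carry no test.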

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

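The tests of Ace, of the clock genes and of other splits of the arrays were chosen after the results they concern had been seen, as were those of Dnajb12 except the count of its low probe sets.

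Ace, the gene of the angiotensin-converting enzyme, was higher in strains F and LF than in L and FL at day 0. Of its 35 probe sets 33 were higher in F than in L (median 1.73), 33 were lower in FL than in F and 32 higher in LF than in L, which argues against sequence variants under a few probe sets. After quantile normalization FL minus F was -1.28 ± 0.12 (limma adjusted p = 1.85e-09, -1.35 before), which argues against a scaling of the arrays, and 0 of the 20 nearest measured genes on the chromosome passed in FL minus F or LF minus L over the mean of 3 times, which argues against a shift of all neighbours. The called genes of LF minus L over the mean of 3 times lay more often on chromosome 10, that of Ace, than elsewhere (14 of 677 tested, odds ratio 3.83, two-sided Fisher's exact test, adjusted p = 0.00245), so a difference at other places on that chromosome stays open. That mean takes in differences of response. Havcr1, on chromosome 10, was at 5.05 in LF and 4.89 in L at day 0, and at 8.92 and 6.42 at day 10. Krt19, Ace and Cacng5, on the same chromosome, were already called in LF minus L at day 0. The day 0 test of chromosomes took FL minus F and LF minus L together, and chromosome 10 did not pass (4 of 677, odds ratio 2.06). LF minus L alone was not tested at day 0, so the excess is not shown to be present before treatment. The control of Ace itself was not tested, and the genotype at this gene is not given in the labels, so the cause stays open.

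Clock genes stood apart in strain LF at day 0. The arm of the clock in the opposite phase moved by -0.85 ± 0.16 in LF against the mean of the other strains while the output arm moved by 0.89 ± 0.10 (SE), so a scaling of the arrays, which moves both alike, cannot give the pattern. The clock score of LF minus L was -0.0471 ± 0.16 over days 7 and 10 against 1.88 ± 0.23 at day 0, which argues against a strain difference present at every time. All 4 LF day 0 arrays had scores (2.72 to 3.07) outside the range of the other 12 day 0 arrays (0.685 to 1.72). Collection at another time of day and a true shift of phase in the untreated LF animals would both give this, and they cannot be told apart, since the labels give no time of day.

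Dnajb12, a co-chaperone gene, was low in strain FL at day 0 and not at days 7 and 10. Of its 23 probe sets 19 were lower by over 1 log2 unit in FL than in F (median -2.26), which argues against a few failed or variant probe sets. By correlation over 200 genes that part the strains, 4 of 4 FL day 0 arrays lay nearest FL, as 16 of 16 day 0 arrays lay nearest their own strain, which argues against arrays of another strain under the FL name, although this measure replaced a distance that had placed fewer arrays rightly. Of the 10 nearest measured genes 0 were lower by over 1 (lowest Ddit4, -0.85), which argues against the loss of a stretch of the chromosome. No biological explanation was tested, and the cause stays open.

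Single arrays lay far from the other 3 of their group in 5 of 72 sets of 4 arrays, which were the array median and the values of Cyp1a1, Ace, Agt, Havcr1 and Dnajb12 in each of the 12 groups, where chance gives about 1 in 20. Cyp1a1 was 4.98 in F day 0 replicate 4 (nearest other 4.44) and 5.75 in FL day 10 replicate 4 (nearest other 6.80). Ace was 7.42 in F day 0 replicate 3 (nearest other 7.58), Agt was 7.28 in F day 10 replicate 1 (nearest other 7.00), and Dnajb12 was 7.40 in FL day 0 replicate 4 (nearest other 5.06, lowest 4.65).

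Responses differed between strains by a test of the difference for 16 genes over all strains and times, for 1 gene in the day 10 response of FL minus that of F (Dnajb12, 2.71) and for 3 genes in that of LF minus that of L (Lcn2, 1.93, Ces1e, -1.55, and Acaa2, -0.90). The Dnajb12 difference lies in its low FL day 0 values. Among 6995 probe sets with several or no gene symbols, which the report's comparisons leave out, limma called 72 for day 10 against day 0 (45 higher and 27 lower) and 144 for F minus L (67 higher and 77 lower).

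Other splits of the same arrays were counted for each number of called genes, and the real split counts as 1. A share under 5% of splits was the bound, not adjusted for the number of results. Of the 35 splits into 4 and 4 arrays, taken without regard to the replicate number, 1 gave as many genes as the real one, so chance can be excluded over these, for F at day 7 (55 genes, highest other 1) and day 10 (30, highest other 2), FL at day 7 (12, highest other 3), and LF at day 7 (195, highest other 5) and day 10 (83, highest other 1). The same was so for F minus L (108, highest other 0), FL minus F (6, highest other 3), LF minus L (20, highest other 1), FL minus L (113, highest other 6), LF minus F (145, highest other 0) and FL minus LF (202, highest other 2). For the lists of F minus L the real split alone gave 6, but the highest other gave 5, so chance is not excluded for any single list. It cannot be excluded for FL at day 10, where 8 of 35 splits gave 2 genes or more and the highest other gave 130. For L at day 7 and day 10, with 0 genes called, 35 of 35 splits are as large by construction (highest other 0 and 1), which tests nothing. Of the 35 splits 8 part the arrays within all replicate numbers, as the real one does, too few for a share under 0.05. In these the highest other was 0 and 2 for F at days 7 and 10, 2 and 2 for FL and 0 and 0 for LF. It was 0 for F minus L (4 for its lists), 1 for FL minus F, 0 for LF minus L, 1 for FL minus L, 0 for LF minus F and 2 for FL minus LF.

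Of 100 random splits chance can be excluded for the number of genes at day 7 (1 split, 398 genes, highest other 3) and day 10 (2, 184 genes, highest other 429). For the number of lists the real split alone reached the count at day 7 (1, 15 lists, highest other 12). In these splits alone it also did at day 10 (1, 12 lists, highest other 11). Other splits thus called nearly as many lists, so chance is not excluded for any single list. Chance can be excluded for the number of genes in the interaction (1, 16 genes, highest other 5). The response of LF minus that of L also lay under the bound (3, 3 genes, highest other 4). With that bound not adjusted over results, and 0 genes called without the arrays of replicate 2, chance is left open there. For probe set use in F minus L the real split alone of 40 reached its count (1, 422 genes, highest other 283). Another split thus called many genes too, and without the arrays of replicate 3 the count was 240. The count does not show which of these genes are beyond chance. Chance cannot be excluded for day 10 against day 7 (5, 6 genes, highest other 2435) and the lists of the response of F minus that of L (11, 6 lists, highest other 8). Nor can it be for the response of FL minus that of F (6, 1 gene, highest other 1120) and probe set use at day 10 (6 of 40, 32 genes, highest other 1361). For the response of F minus that of L, with 0 genes called, 100 of 100 are as large by construction (highest other 1). For the chromosome test 1 of 100 gave as many chromosomes (1, highest other 0), but 80 of the 99 other splits called 0 genes where the real one called 25, so no chromosome could pass in most of them and the splits do not decide. Splits with 130, 429, 1120, 1361 and 2435 genes point to a structure of the arrays beyond their groups, and the highest value varies with the draw. In 100 splits that part arrays as the real one does, within replicate numbers, 1 was as large for day 7 (highest other 350), 1 for its lists (13), 1 for day 10 (30) and 5 for its lists (12), and 3 for day 10 against day 7 (12). For responses 10 were as large for the lists of F minus L (8), 11 for FL minus F (1), 3 for LF minus L (4) and 1 for the interaction (2). The bound of 5% is thus passed for day 10 against day 7 only within numbers and for the day 10 lists only in the other splits, so chance is left open for both. The chromosomes and probe set use had no splits within numbers.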

How the results depend on the processing

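Alternatives without strain LF, over the mean of 3 times and over days 7 and 10 were chosen after seeing the data, and the others before the data were examined. The cause of a change was not tested, except that a fit on fewer arrays has fewer to estimate the spread. Of 188 results of genes named for their size of change or in every comparison, 187 kept direction and call with the replicate block, 177 with the mean of probe sets, 183 after quantile normalization and 156 on the groups compared alone, as did 184 of 184 without the dimmest genes. With a replicate number left out 589 of 752 did, and with an array left out 2494 of 2736. Ace at day 7, at day 10 and in LF at day 7 was counted as a list member, outside these 188, and gained a call under the block (adjusted p = 0.0203, 0.0296 and 0.0219). The self-test had changes of 0.5 log2 units recovered in 12% of genes for the day 10 response of F minus that of L and in 18% for the interaction.

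With the replicate block the counts became 894 for day 7, 52 for F at day 10, 1 for L at day 10, and 19 and 4 for FL at days 7 and 10. They became 683 for LF at day 7, 11 for FL minus F, 185 for FL minus L, 239 for LF minus F, 384 for FL minus LF, 11 for the response of LF minus L, 28 for the interaction and 0 chromosomes. With the mean of probe sets they were 12 for day 10 against day 7, 6 for FL at day 10 and 1 for the response of LF minus L. Without the dimmest genes they were 12 for day 10 against day 7, 4 for FL at day 10, 8 for the response of LF minus L, 18 for probe set use at day 10 and 0 chromosomes. After quantile normalization they were 349 for day 10, 121 and 66 for F at days 7 and 10, 2 for L at day 10, 20 and 5 for FL, and 336 and 151 for LF. Between strains they were 222 for F minus L, 11 for FL minus F, 42 for LF minus L, 228 for FL minus L, 320 for LF minus F, and 403 for FL minus LF. For responses they were 2 for FL minus F, 13 for that of LF minus L, 32 for the interaction, 2 lists for the response of F minus L and 0 chromosomes. On the groups compared alone they were 0 for day 10 against day 7, 16 for F at day 10, 2 and 1 for FL, 66 for LF at day 7, 71 for F minus L and 1 for FL minus F. They were also 11 for LF minus L, 74 for FL minus L, 0 for the response of FL minus F and 0 chromosomes. With an estimated correlation 1 list passed for day 7, 1 for day 10, 0 for F minus L and 0 for the response of F minus L.

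Without strain LF the counts were 67 for day 7, 76 for day 10, 0 for day 10 against day 7 and 3 for the interaction. Over the mean of 3 times they were 562 for F minus L, 28 for FL minus F and 54 for LF minus L, or 813, 76 and 78 under the block. Over days 7 and 10 they were 46 for LF minus L, 339 for LF minus F and 415 for FL minus LF. Over days 7 and 10 the sign turned for Dbp (-0.0325), Bhlhe41 (-0.0522) and Ndrg1 (0.00388) in LF minus L, for Cyp1a1 in LF minus F (-1.61) and in FL minus LF (from -0.23 to 0.47), and for Dnajb12 in FL minus LF (0.0442).

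With an array or a replicate number left out the counts ranged as follows. Day 7 gave 71 to 674, day 10 76 to 220 and day 10 against day 7 0 to 55. Within strains, F gave 16 to 48 and 5 to 28, L 0 to 3 and 0 to 2, FL 4 to 15 and 1 to 9, and LF 23 to 403 and 25 to 77. F minus L gave 43 to 114, FL minus F 3 to 8, LF minus L 9 to 24, FL minus L 43 to 199, LF minus F 63 to 141 and FL minus LF 70 to 355. Responses gave 0 to 1 for F minus L, 0 to 2 for FL minus F and 0 to 5 for LF minus L, the interaction 0 to 24 and the chromosomes 0 to 1. Lists gave 13 to 14 for day 7, 11 to 13 for day 10, 3 to 6 for F minus L and 1 to 8 for the response, and probe set use 240 to 387 for F minus L and 12 to 42 for day 10.

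Single arrays moved these counts by over 1.5 times. Day 7 gave 674 without L day 0 replicate 4. F at day 7 gave 35 without F day 0 replicate 4 or F day 7 replicate 1. F at day 10 gave 7 without F day 0 replicate 2, 9 without any other F day 0 array or F day 10 replicate 4, and 15 and 17 without F day 10 replicates 1 and 3. L at day 10 gave 2 without L day 0 replicate 4. FL at day 10 gave 1 without FL day 0 replicate 1, 2 or 3, 4 without replicate 4 of either day, and 9 without FL day 10 replicate 1. LF at day 7 gave 98, 60 and 294 without LF day 0 replicates 1, 2 and 4, and 107 and 92 without LF day 7 replicates 2 and 3. LF at day 10 gave 41 and 54 without LF day 0 replicates 1 and 2, and 40, 52 and 48 without LF day 10 replicates 1, 2 and 4. F minus L gave 70 without F day 0 replicate 4, LF minus L 13 without LF day 0 replicate 2 or L day 0 replicate 1, FL minus L 69 without L day 0 replicate 3, and FL minus LF 128, 124 and 112 without FL day 0 replicate 3 and LF day 0 replicates 1 and 2. The response of F minus L gave 1 without F day 10 replicate 4, that of FL minus F 2 without FL day 0 replicate 4, and that of LF minus L 1 without L day 0 replicate 2 or 3 or LF day 10 replicate 4, and 5 without L day 10 replicate 3. The interaction gave 9 and 10 without LF day 10 replicate 4 and LF day 7 replicate 3. Day 10 against day 7 gave 55, 19, 15, 13 and 11 without FL day 10 replicate 4, L day 10 replicate 2, F day 10 replicate 4, LF day 10 replicate 2 and L day 10 replicate 1. It gave 3 without FL day 10 replicate 2, LF day 7 replicate 1 or L day 7 replicate 1. It gave 2 without FL day 10 replicate 1, LF day 10 replicate 3, F day 10 replicate 3, L day 10 replicate 4, FL day 7 replicates 1 or 3, or F day 7 replicates 1, 3 or 4. It gave 1 without LF day 10 replicate 1, LF day 7 replicate 2 or L day 7 replicate 3. It gave 0 without FL day 10 replicate 3, LF day 10 replicate 4, F day 10 replicates 1 or 2, L day 10 replicate 3, FL day 7 replicate 4, LF day 7 replicates 3 or 4, F day 7 replicate 2, or L day 7 replicates 2 or 4.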

Other observations

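The tests of chromosomes over the mean of 3 times, and the genes singled out over several times, were chosen after the results were seen.

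Other gene groups moved with induction in parts. Among 22 tubular injury genes at day 10, means over strains, those that rose included Cdkn1a (log2 change 0.91), Gpnmb (0.65), Cd44 (0.51), Lgals3 (0.40), Anxa2 (0.37), Vim (0.35) and Krt8 (0.27), and Tff3 fell (-0.30). The matrix genes Lum (0.74 ± 0.11, SE, n = 16 arrays against 16) and Timp1 (0.78 ± 0.10) rose at day 10, 2 of 19 members of their list (3 rose and 1 fell when adjusted over the list alone), and the list did not pass (limma camera adjusted p = 0.142). At day 7 the endothelial genes Emcn (-0.32 ± 0.07), Plvap (-0.27 ± 0.07) and Podxl (-0.21 ± 0.05) fell, 3 of 12 members (4 when adjusted over the list alone), in a list that did not pass (adjusted p = 0.0521). The cholesterol synthesis genes Idi1 (-0.33 ± 0.10) and Msmo1 (-0.29 ± 0.08) fell at day 7, 2 of 12 members (3 when adjusted over the list alone, adjusted p = 0.00313, adjusted p = 0.445 with an estimated correlation), while at day 10 0 of 12 passed. Ccnd1, which drives entry into the cell cycle, fell at day 7 (-0.63 ± 0.09) and at day 10 (-0.56 ± 0.09), and the interferon-induced chemokine Cxcl9 fell at both times (-0.37 ± 0.08 and -0.39 ± 0.08) while Cxcl11 rose at day 10 (0.37 ± 0.10).

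Grik2 and Pitpnm1 differed between strains in the same direction at all 3 times. Grik2 was at 3.57 ± 0.13, 3.39 ± 0.16 and 3.44 ± 0.14 in strain LF at days 0, 7 and 10 (SD, n = 4), and between 4.65 and 5.11 in the groups of other strains (LF minus L, mean of 3 times, -1.33, limma adjusted p = 5.12e-12). Pitpnm1 was at 6.21 ± 0.16, 6.19 ± 0.30 and 6.30 ± 0.20 in strain FL, and at 7.12 ± 0.29, 6.97 ± 0.31 and 7.11 ± 0.31 in F. Over the mean of 3 times 5 genes passed in both FL minus F and LF minus L, all in opposite directions, namely Ace (-1.08 and 0.87), Cacng5 (0.87 and -0.59), Clu (-0.54 and 0.62), Gpnmb (-0.52 and 0.48) and S100a10 (-0.38 and 0.35). A mean over times also takes in differences of response. Clu was at 8.47 ± 0.16 in LF and 8.57 ± 0.22 in L at day 0, and at 10.31 ± 0.31 and 9.05 ± 0.50 at day 10. At day 0 LF minus L was -0.01 ± 0.20 for Gpnmb and 0.18 ± 0.15 for S100a10 (SE, adjusted p = 1 for both).

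Called genes of LF minus L over the mean of 3 times lay more often on chromosome 10 than elsewhere (14 of 677 tested, odds ratio 3.83, two-sided Fisher's exact test, adjusted p = 0.00245). This mean also takes in differences of response, as for Havcr1, which lies on chromosome 10. For FL minus F 4 of 677 were called there (odds ratio 1.88, adjusted p = 0.991), and 0 chromosomes passed. For F minus L chromosome 2 held more calls (60 of 450, odds ratio 2.16, adjusted p = 2e-05) and chromosome 1 fewer (48 of 1184, odds ratio 0.517, adjusted p = 4.95e-05).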
